A study of Beauveria bassiana with 2 samples.

How the data were processed

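The material was RNA of Beauveria bassiana, a fungus that kills insects, from strain ARSEF2860. Per the labels' protocols, conidia (5 µl at 100000 conidia per ml) were injected into the body cavity of Galleria mellonella, the greater wax moth, and infected insects were kept at 25 °C for 3.5 days. Haemolymph was then collected by centrifugation, so that each sample mixed hyphal bodies, the yeast-like cells the fungus forms in haemolymph, with cells of the host. Total RNA was extracted with TRIzol and made into double-stranded cDNA, per the labels. Per the series design text, fungal reads were sorted from host reads by mapping to the fungal genome and were assembled into a transcriptome. How the assembly relates to the gene list is not given in the sources used here. The aligner, the counting tool, the annotation version and whether strand was used are not given in the sources used here. The host side of the data was not analysed here.

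The table used holds 9463 genes with a coding length, a read count and an RPKM value for each of 2 replicates. The counts were deposited by the authors as raw whole reads per gene, with a dash for a gene without reads in that replicate, which was read as 0. The RPKM values were deposited by the authors beside the counts. All 9463 values in each replicate equalled the RPKM formula applied to the gene's reads, its coding length and the replicate's own summed gene reads, within a relative tolerance of 1e-09. The last column of the deposited table carries the heading of replicate 1 a second time. Its values matched the reads of replicate 2 in all 9463 rows and no non-zero value matched those of replicate 1, so it was used as replicate 2. Lengths were multiples of 3 in 100% of rows, so they are called coding lengths here and hold no untranslated regions.

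Neither the table nor the RefSeq gene table of assembly ASM28067v1, in which all 9463 locus tags were found, pairs a tag with a description. For this reason 40 gene lists fixed as text patterns before the data were examined could not be filled, and neither the ratios of list medians nor the percentiles planned for them were computed. The naming rule, also fixed before the data were examined, took the 20 genes with the highest mean RPKM, the 5 genes differing most in each direction between replicates, up to 4 members of each filled list and every member of the oosporein cluster. The 20 most abundant genes are shown by tag in a plot. In the text only a few tags without a name are given, since the sources used here do not say what those genes encode. The oosporein list (BBA_08179 to BBA_08185, OpS1 to OpS7) was fixed by tag before the data were examined. Tags of tenellin synthetase, bassianolide synthetase, brlA, abaA and wetA were added once the table was seen to hold no descriptions, after reading their coding lengths and before reading their expression values. The names attached to these tags come from published knowledge of this fungus, not from the sources used here, and were not checked against sequence. The values belong to the tags whether or not a name holds. RefSeq positions served only to tell which genes neighbour each other, and no coordinates are printed because the build used by the authors is not given in the sources used here. A drop in start position between consecutive tags was taken as the start of a new sequence, which can miss a boundary where positions happen to rise across it.

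The 2 samples form 1 group and there is no second condition, so levels were described and no test between groups was made. A gene was called detected at RPKM of at least 1 in both replicates. Differences between replicates were taken on log2(RPKM + 1), which understates changes of weakly expressed genes, for genes with mean RPKM of at least 10. A pseudocount of 1 and a 2-fold threshold were used. The place of the oosporein list was given as the percentile of its median among 10000 random lists of the same size. Genes are not replicates, so this percentile describes these libraries and is not a p-value. Flanking genes were up to 10 listed genes on each side of the cluster on the same sequence. Intervals on single counts are exact 95% Poisson intervals, intervals on ratios of counts are exact binomial (Clopper-Pearson), and a count of 0 was taken to allow 3 reads, a limit somewhat below the upper end of the exact Poisson interval. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

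Counted reads came to 9753845 in replicate 1 and 6359333 in replicate 2. At the median coding length of 1302 bases, RPKM 1 corresponded to 12.7 reads in replicate 1 and 8.28 reads in replicate 2. RPKM denominators equalled the sums over the listed genes, so no counted read lies outside the rows used. A further 901 RefSeq genes are absent from the list, hold no counted read and were not analysed here. Whether the authors' gene set included them is not given in the sources used here. Every listed gene had a read in at least 1 replicate, so shares of listed genes are shares of genes with a read. The step that counts replicate differences was tested on simulated libraries with the real gene levels and depths and with counting error alone. With 200 genes changed 4-fold, 100% passed the 2-fold threshold and 0 unchanged genes did. With 200 genes changed 1.5-fold, 0% passed. At that low noise such outcomes follow from the threshold, so the test checks the arithmetic of the step and says nothing of its error at the wider spread of the real replicates.

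Alternatives fixed beforehand were other detection thresholds, pseudocounts and minimum levels, centring, rescaling to TPM, reads in place of RPKM, length-matched random lists, other list summaries and leaving out each replicate. Leaving the ribosomal protein genes out of the abundance share was also planned and was not run, because no source used here identifies them. The comparison of the cluster with its flanking genes, the medians around the synthetase genes, the windows of neighbouring genes, the long genes and the neighbour and length relations, with their alternatives, were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.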

Results

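The transcriptome of Beauveria bassiana growing in the haemolymph of the greater wax moth was measured by RNA-seq 3.5 days after conidia were injected. The data comprise 2 replicates of 1 group, in vivo hyphal bodies. The labels call them replicate experiments but do not say whether each came from a separate pool of insects. Fungal genes held 9753845 reads in replicate 1 and 6359333 reads in replicate 2, with a median of 221 and 119 reads per listed gene. With 1 condition measured, the values below are levels in these cells and say nothing of change relative to another growth stage. All levels below are mean RPKM ± SD (n = 2) unless a replicate is named.

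The gene cluster for oosporein, a red pigment and toxin made by a polyketide route, was transcribed well above the typical gene in the hyphal bodies. The names OpS1 to OpS7 and the functions given here are from published knowledge, and the table lists tags alone. All 7 genes were detected in both replicates, with a median RPKM of 304.4 in replicate 1 and 303.4 in replicate 2, and 4 of the 7 lay in the top 10% of all genes. OpS5 (BBA_08183), a laccase gene, was the highest, at 1448 ± 94.3 RPKM (23889 and 17079 reads), above 98.8% of listed genes. OpS6 (BBA_08184), a glutathione S-transferase, followed at 620 ± 135. OpS2 (BBA_08180) stood at 456 ± 144 and OpS7 (BBA_08185) at 303.9 ± 0.76. The polyketide synthase gene OpS1 (BBA_08179, 6636 coding bases) had 91.7 ± 35.1 RPKM from 7543 and 2825 reads. OpS4 (BBA_08182) had 74.4 ± 15.2, and the cluster's transcription factor gene OpS3 (BBA_08181) was the lowest, at 56.7 ± 18.9. OpS5 exceeded OpS1 by 11.9-fold in replicate 1 (95% interval 11.6 to 12.2) and by 22.6-fold in replicate 2 (21.7 to 23.6). Its excess over OpS3 was 19.7-fold (18.7 to 20.8) and 34.9-fold (32.2 to 37.9). These ratios thus differed between replicates by more than counting error, while their direction was the same in both. Of the 7 genes, 0 differed by more than 2-fold between replicates, as deposited, centred or rescaled to TPM. The ratio of replicate 2 to replicate 1 ran from 0.57 for OpS1 to 1.36 for OpS6, and the number of genes higher in replicate 2 was 2 as deposited, 3 when centred and 1 after rescaling to TPM.

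The genes that border the cluster were lower than each of its members. The adjacent genes BBA_08178 and BBA_08186 had mean RPKM 17.6 and 11.7. The cluster median was 20.1 ± 2.10 times the median of the 16 flanking genes (18.7 in replicate 1 and 21.6 in replicate 2), of which 1, BBA_08194 at 99.5, lay above the cluster members OpS1, OpS3 and OpS4. The comparison with flanking genes was chosen after the values were seen. Against 10000 random lists of 7 genes the cluster's median reached percentile 99.98, and 2 random lists were as high. Random lists break up neighbouring genes, whose levels correlate. Among 6064 windows of 7 neighbouring listed genes, an alternative chosen after seeing the data, 7 had a higher median, 2 an equal median (the cluster itself and the window that starts at OpS2) and 6055 a lower median, so 99.85% lay below the cluster. The cluster held 0.46% ± 0.019 of all reads, 45844 reads in replicate 1 and 28174 in replicate 2.

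**Figure D1:**
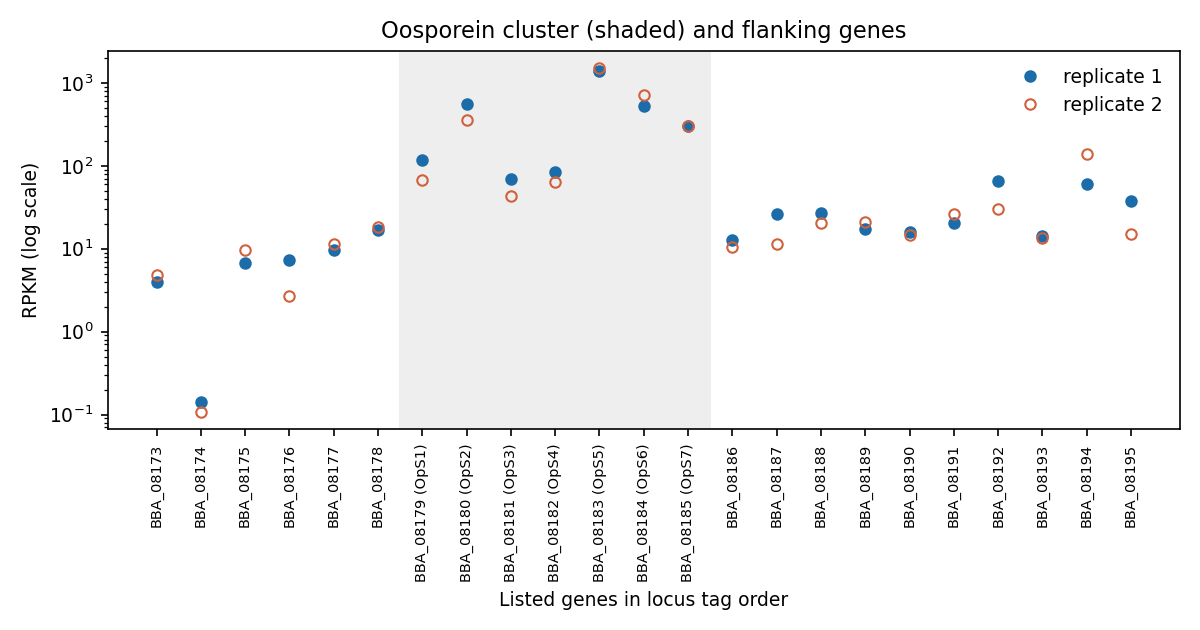
RPKM (log scale) of the 7 oosporein genes (shaded) and the 16 listed genes beside them in locus tag order, with a point per replicate. The 7 genes lie between 43.4 and 1515 RPKM, and the adjacent genes BBA_08178 and BBA_08186 at means of 17.6 and 11.7.

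Genes for the core enzymes of 2 other secondary metabolites, named from published knowledge, had almost no reads. Bassianolide synthetase (BBA_02630), the non-ribosomal peptide synthetase of the cyclic depsipeptide bassianolide, had 4 and 2 reads over 9444 coding bases, or 0.043 RPKM (95% interval 0.012 to 0.11) and 0.033 RPKM (0.0040 to 0.12). The tenellin synthetase gene (BBA_07338), which encodes a hybrid polyketide and peptide synthetase of the yellow pigment tenellin, had 6 reads over 12708 coding bases in replicate 1, or 0.048 RPKM (0.018 to 0.11). It had 0 reads in replicate 2, which allows up to 0.037 RPKM by the limit of 3 reads and 0.046 RPKM by the exact interval. In replicate 1, OpS1 exceeded tenellin synthetase by 2407-fold (1106 to 6562) and bassianolide synthetase by 2684-fold (1048 to 9852). In replicate 2 OpS1 was 2010-fold higher than bassianolide synthetase (556 to 16607). Against tenellin synthetase, with 0 reads there, the lower limit of the same exact interval was 1466-fold, and the fold against a limit of 3 reads in that library was 1803. The intervals lie far from 1 in both replicates and cover counting error only. Around tenellin synthetase, 7 of 20 neighbouring listed genes were below RPKM 1 in both replicates, and their median was 1.33 RPKM. Around bassianolide synthetase 5 of 20 were below 1 and the median was 9.43 RPKM. Of all listed genes 13.4% were below RPKM 1 in both replicates, as was 1 of the 16 genes flanking the oosporein cluster. These surroundings were chosen after the values were seen.

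Regulators of conidiation, the formation of aerial spores, differed in level (names from published knowledge). brlA (BBA_07544), an activator of the central conidiation pathway, had 87.1 ± 14.3 RPKM, above 83.9% of listed genes. abaA (BBA_00300) and wetA (BBA_06126), further regulators of that pathway, had 5.32 ± 2.18 and 6.58 ± 0.97 RPKM, below the median gene. brlA exceeded abaA by 11.2-fold in replicate 1 (9.55 to 13.3) and by 25.7-fold in replicate 2 (19.9 to 33.7). It exceeded wetA by 10.6-fold (8.84 to 12.8) and 16.5-fold (12.9 to 21.3). The order of brlA above both was the same in each replicate, while the sizes of both ratios differed between replicates, with intervals that did not overlap.

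Most listed genes were detected. Fungal reads were sorted from host reads by mapping to the fungal genome, and whether host reads remained among them was not checked. Of 9463 genes with at least 1 read in either replicate, 7669 (81.0%) reached RPKM 1 in both replicates, with 8003 doing so in replicate 1 and 7864 in replicate 2. A set of 1265 genes stayed below RPKM 1 in both. The 901 RefSeq genes outside the list hold no counted read and are not part of these counts. The median gene had a mean RPKM of 15.5, and the lower and upper quartiles lay at 2.69 and 50.02. A mean RPKM of at least 100 was reached by 1343 genes and of at least 1000 by 149 genes.

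Transcript abundance was concentrated in few genes. The 100 most abundant genes made up 48.7% ± 5.42 of summed RPKM, from 44.9% in replicate 1 to 52.6% in replicate 2, and 32.2% ± 3.91 of reads. The 10 most abundant made up 13.5% ± 3.22 of summed RPKM. The lists of the 100 highest genes of each replicate shared 87 members, and those of the 20 highest shared 14. The highest mean RPKM belonged to BBA_08576, at 24440 ± 16675, followed by BBA_09309 at 21068 ± 10781 and BBA_02388 at 16790 ± 2808. For BBA_08576 the replicates were 2.86-fold apart (12649 and 36232), so its rank at the top rests on replicate 2, whereas BBA_02388 differed by 1.27-fold. In replicate 1 the highest was BBA_02388. BBA_05586 had the most reads in replicate 1, 210510 over 1971 coding bases, and a mean RPKM of 9569 ± 1953. The sources used here do not say what these genes encode. Of the 20 most abundant genes, 18 were higher in replicate 2, as deposited and relative to the median gene, and 17 after rescaling to TPM. The ranking mean includes replicate 2 and favours genes very high in 1 replicate, so this count may partly follow from the ranking. The median coding length of the 100 most abundant genes was 498 bases, against 1302 bases for all listed genes.

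**Figure D2:**
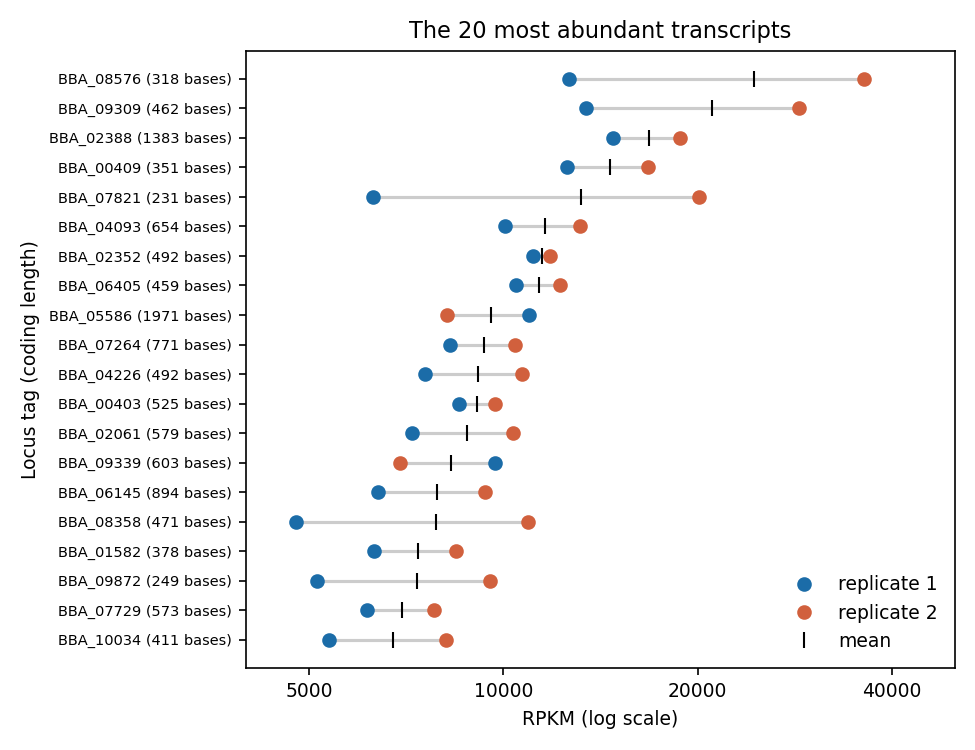
RPKM (log scale) of the 20 genes with the highest mean, with a row per locus tag with its coding length; circles are the replicates and the black tick is their mean. Means run from 6760 to 24440, and 18 of the 20 genes lie higher in replicate 2 as deposited (17 after rescaling to TPM).

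The replicates ranked the genes alike. Across the 9463 genes Pearson's r of log2(RPKM + 1) was 0.976 and Spearman's rho was 0.974. These coefficients are across genes, which are not independent replicates. Among 5476 genes with mean RPKM of at least 10, 75.7% differed by less than 1.5-fold and 414 (7.56%) by more than 2-fold. As deposited, 152 of these were higher and 262 lower in replicate 2, and the median gene lay at -0.17 (log2) in replicate 2. Relative to that median, 241 were higher and 151 lower, so the balance between directions turns with the centring. After rescaling to TPM, which moved the median to -0.35, 89 were higher and 405 lower. The largest differences were BBA_04096 and BBA_08970, at 3.01 and 2.61 on the log2(RPKM + 1) scale higher in replicate 2. BBA_00382 and BBA_05491 lay at -2.44 and -2.37 on that scale, the value of BBA_05491 resting on 7 reads in replicate 2. The SD of the log2 difference was 0.53, against a mean of 0.11 in 100 simulated pairs of libraries that held counting error alone, in which at most 3 genes differed by more than 2-fold. A chi-square of 467382 on 8426 degrees of freedom over genes with at least 10 reads showed a difference beyond sampling noise, as any separate library preparations would give, so they are not 1 library deposited again. They were counted as 2 samples because the labels name 2 replicate experiments. No difference between the replicates has a replicate check of its own.

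**Figure D3:**
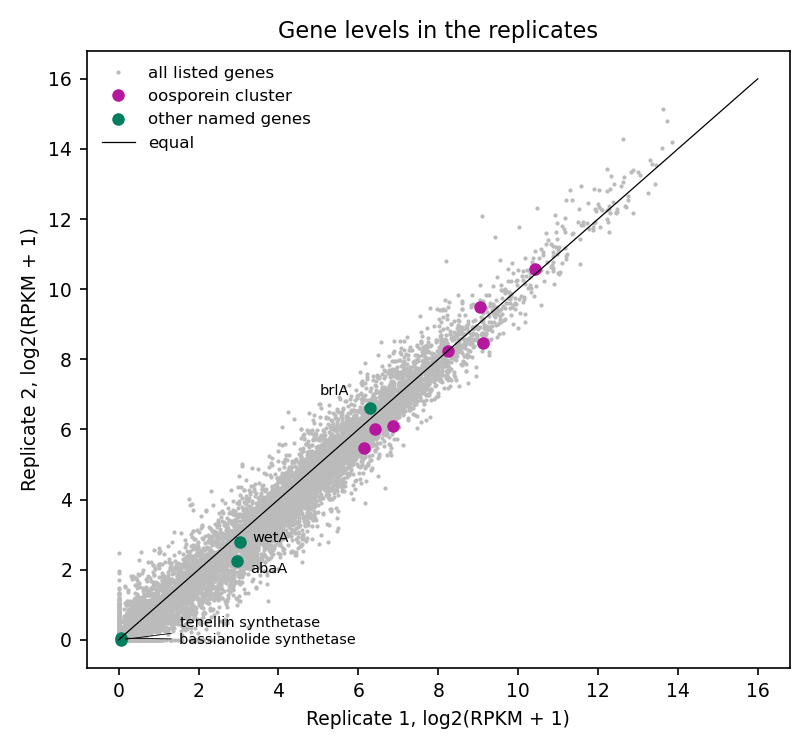
Levels of all 9463 genes in replicate 1 and replicate 2 as log2(RPKM + 1), with the oosporein cluster and 5 other named genes marked and a line of equality. The cluster lies at mean RPKM 56.7 to 1448, while tenellin synthetase and bassianolide synthetase lie next to the origin.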

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

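The alternatives on windows of neighbouring genes and on flank size, neighbour correlation and length trend were chosen after the results were seen. Of 23 alternative values for 8 results, not counting those that leave out a replicate, 10 stayed within a set bound and 13 moved further. The bound was 1 SD of the replicates, but 1.5 times for counts of genes, equality to 2 decimals for Pearson's r and 0.05 for the length trend. Reversal was labelled for the length trend alone, where 0 reversed. The turn in direction of the replicate differences on centring was thus not counted. For detected genes the upper bound lay above all 9463 listed genes. For the percentile the SD was below the smallest step that 10000 lists allow. The tally therefore reflects these bounds and does not measure stability. With 2 replicates, leaving out either moves a mean by a fixed fraction of its SD, so it says nothing of the stability of the levels of the named genes or of the excess over flanking genes. Detected genes numbered 6099 at a threshold of 5 and 8785 at 0.1. Pearson's r of the replicates was 0.958 with a pseudocount of 0.1 and 0.968 for genes with mean RPKM of at least 1. Genes more than 2-fold apart numbered 775 at mean RPKM of at least 1 and 150 at mean RPKM of at least 50, since the minimum sets how many genes are compared. The 100 genes with the most reads held 36.0% of reads, against 48.7% of summed RPKM for the 100 most abundant genes. The percentile of the oosporein cluster was 99.99 with the mean of log2(RPKM + 1) and with lists matched on coding length, 99.97 among genes with mean RPKM of at least 1, 99.98 to 99.99 on leaving out a replicate, and 99.85 among windows of 7 neighbouring genes. Its excess over flanking genes was 23.9-fold with 5 genes on each side and 16.2-fold with 20. Except where stated, the cause of these shifts was not tested. Leaving out ribosomal protein genes, and the ratios of list medians with their geometric means, level filter and left-out replicates, were not run because no source used here identifies the genes. No paired analysis was possible because there is 1 group. Depth limits the least expressed genes, since 3 reads at the median coding length amount to 0.24 RPKM in replicate 1 and 0.36 RPKM in replicate 2.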

Other observations

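High levels ran in stretches of neighbouring genes elsewhere in the genome too, at tags chosen after their values were seen. Among 6064 windows of 7 neighbouring listed genes, 7 had a higher median than the oosporein cluster and 0 had a higher lowest member. The window with the highest median, BBA_09649 to BBA_09655, reached 686 RPKM but held a gene at 7.47 RPKM. Stretches of at least 4 neighbours in the top 10% of genes numbered 8, against a mean of 0.67 and a highest count of 4 in 1000 shuffled gene orders. The longest was BBA_07198 to BBA_07203, with 6 genes. The longest in any of the 1000 shuffled orders was 7, and how often they reached 6 was not recorded, so its length alone cannot be judged. Stretches of at least 5 genes below RPKM 1 in both replicates numbered 2, against a mean of 0.24 and a highest count of 3 in the shuffled orders. How often the shuffled orders held 2 or more was not recorded. A tag absent from the list ended a stretch, in the real and the shuffled orders alike. Stretches that span unlisted genes were therefore missed, and the count of 2 may be too low. Of 21 genes with at least 9000 coding bases, a class chosen after tenellin synthetase and bassianolide synthetase were seen near 0, 7 were below RPKM 1 in both replicates. Without those 2 genes it was 5 of 19, against a mean of 2.53 in random lists, and 990 of 10000 lists held as many or more, so the other long genes did not stand clearly apart.

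The tests of chance order, counting error, library preparation, abundance in separate groups of genes and division by length were chosen after the result was seen. Those of shared reads and of unexpressed stretches were not. Adjacent genes correlated at r = 0.25 across 8705 pairs on log2(RPKM + 1), and genes 10 tags apart at 0.0088. Chance order is argued against, since the highest of 10000 shuffled orders gave 0.045, and so are stretches of unexpressed genes alone, since pairs detected in both replicates gave 0.16 (bootstrap SE 0.014). Reads shared by close genes are argued against as the whole cause, because pairs more than 2000 bases apart still correlated at 0.16 (SE 0.025), but part of the relation may rest on them, as r was 0.38 (SE 0.052) for pairs under 200 bases apart. Reads shared by tandem copies stay open, and no biological explanation was tested because the design has 1 group.

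Short genes were relatively higher in replicate 2, with a rank correlation of coding length and log2 difference of -0.20 across genes with mean RPKM of at least 10. The median log2 difference was 0.26 in the shortest 10% of these genes and 0.038 in the next 10%. Among the longer genes, in steps of 10%, it lay between -0.27 and -0.12. The longest 10%, at -0.19, did not lie lowest, so the shift was mainly one of the shortest genes. Counting error is argued against, since the lowest of 100 simulated pairs of libraries gave -0.038. A test of abundance as the explanation was set beforehand to be read over all 5 equal groups of genes by mean RPKM. It gave mixed values, and the groups were parted only then. Abundance is argued against in the 2 most abundant groups (-0.23 and -0.34). In the other 3 (0.038, -0.088 and -0.11) it cannot be told apart, as these lie within or close to the bound of -0.1. The least abundant group, at 0.038 (SE 0.030), did not show short genes relatively higher in replicate 2. A difference in library preparation or RNA integrity may underlie the gap of 0.44 (log2) between the shortest and longest 10% of genes, and cannot be told apart from one between the infected insects, with 1 library from each replicate and no preparation label. No biological explanation was tested.

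The most abundant genes were short, with a median of 498 coding bases among the 100 highest by RPKM. Division by a coding length without untranslated regions would raise RPKM most for short genes if reads on those regions were counted. Whether they were is not given in the sources used here. Such division is argued against as the whole cause. The 100 genes with the most reads, a ranking without that division, had a median of 777 bases, below the lowest of 10000 random lists (933 bases). What these genes encode was not analysed here, and no biological explanation was tested.

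After thinning replicate 1 to the depth of replicate 2, 9162 ± 8.34 genes (SD over 100 thinnings) kept a read, against 9254 before thinning and 9049 in replicate 2.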
